A study of Homo sapiens with 8 samples.

How the data were processed

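ChIP-seq was done on primary human epidermal keratinocytes, crosslinked with DSG and formaldehyde. The 8 libraries were grouped by their labels into KLF3 ChIP (2), CBP ChIP (2), CBP ChIP after KLF3 knockdown (2) and 1 input each for the KLF3 and the CBP experiments. The labels give day 3 of differentiation for all but the knockdown libraries, for which they give no day. Per the submitters' processing notes, reads were aligned with Bowtie2 to hg19 and peaks were called with HOMER, and versions and thresholds are not given in the sources used here. Per the file headers, the KLF3 and CBP lists each come from replicate ChIP and hold 1 list over both replicates. The score of each peak is the authors' own value from the peak caller, on a scale that the deposited lists do not state, so scores were compared within a list only. Each peak comes with the authors' nearest gene and the signed distance of its centre to that gene's transcription start site. Per the file headers, the table of changed CBP regions was made with diffReps from KLF3 knockdown (KLF3i) and control knockdown (CTLi) and holds significant regions only. No library label names a control knockdown, and the labels do not say whether the 2 CBP ChIP libraries served as that control. If they did, CBP peaks, their scores and the losses rest on the same libraries. Its log2 values are, per the file headers, the fold change of knockdown over control, with the normalization not given in the sources used here. Its p-value column is the authors' deposited value per region, and whether it was adjusted is not given in the sources used here. The table holds 6 regions with a deposited p above 0.05, and 51 lost and 25 gained regions whose absolute log2 fold change is small (under 0.5), all at CBP peaks.

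Peaks and regions on chromosomes 1 to 22 and X were used, 25334 of 25352 KLF3 peaks, 24315 of 24357 CBP peaks and 3768 of 3788 changed regions. A promoter peak has its centre within 1 kb of a start site by the deposited distance. Gene names turned into dates by a spreadsheet (47 in the KLF3 list and 44 in the CBP list) were taken as naming no gene, and 95.8% of the 17312 names matched the symbols of a gene table of GRCh38.p14, which was used for names and gene type only, not for positions. A name that is a synonym of several coding genes, or a list member under an older symbol, was left unmatched, LOR among them. Start sites on hg19 were recovered from the peak centres and signed distances. As a check, 98.8% of 16936 CBP peaks were given the same gene by the recovered sites. A changed region took the gene of a CBP or KLF3 peak it overlapped, or else that of the nearest recovered start site, which can be far away and need not be the gene it acts on.

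Overlap means at least 1 shared base. Observed overlaps were set against 1000 rotations of a list along each chromosome, one-sided, with 0.001 the smallest p that these can give. Rotation takes no account of chromatin accessibility or of sequence in which no peak can be called. Shares carry exact Clopper-Pearson 95% intervals and odds ratios Woolf 95% intervals. Comparisons of shares used Fisher's exact test, two-sided, and some p-values were too small for the computer to represent, in which case only the interval is given. Stratified odds ratios are Mantel-Haenszel estimates. These intervals cover counting error over peaks or regions only. Read depth is unknown, peaks and regions are not replicates, and 1 value per peak or region leaves no error between replicates. The 20 gene lists were cornified envelope precursors, suprabasal keratins and late enzymes, epidermal lipid barrier, basal keratinocyte and hemidesmosome, desmosome and adherens junction, epidermal transcription factors, AP-1 and immediate early, Notch, EGFR, TGF-beta and BMP, cell cycle and replication, extracellular matrix and motility, inflammation and interferon, ribosomal proteins, coactivators and KLF3 partners, and markers of melanocytes, fibroblasts, immune and Langerhans cells, neurons and hepatocytes. For bound genes the background was all 20056 protein-coding genes, and for changed genes the 8540 genes with a CBP peak or a changed region. Benjamini-Hochberg adjustment ran over the 20 lists within each class of genes. Some genes, TGM1, TP63 and HES1 among them, are in more than 1 list, so the lists are not independent. Neighbouring genes were counted separately. The methods were tested on simulated data, where a planted odds ratio of 2 came back as 2.005 on average, one of 1 as 0.993, and random placement gave a fold of 0.939 over rotation. The simulated losses followed the same score deciles that served as strata, so confounding within a decile was not checked. Random placement left out no uncallable sequence.

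The tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names the 10 highest peaks per list, the 10 lost and 10 gained regions with the largest absolute log2 fold change, up to 4 members per list and direction by absolute log2 fold change, up to 4 co-bound members per list by KLF3 score, and KLF3, CREBBP and EP300. The report gives a selection of these, and some members of the lists are not reported here. The other members with a lost region and the genes of the epidermal differentiation complex were chosen after their values were seen. So were the values given for IVL, KLF9, KLF10, JUNB and IER5 and for the second regions of CALML5 and CREBBP. The plan was to use an adjusted p under 0.05 for changed regions. With the table already filtered, all regions were used, and the deposited p under 0.05 decided which the rule could name. Alternatives covered promoter windows of 500 bases and 2 kb, overlap of 50% of the shorter interval, centres within 500 bases, gaps of up to 1 kb, score and fold change limits, deposited p limits of 0.01 and 0.001, distances to genes and backgrounds. Strata of CBP score (10 and 50 classes), of crowding within 2 kb and of the number of CBP peaks per gene, a deposited p limit of 0.0001, promoter peaks alone, a region length limit and the resolution of gene names shared by several genes were added after the data were seen. Motifs (13 had been listed) and random placement within promoter or distal classes were not analysed here, for want of a genome and annotation of the same build. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.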

Results

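KLF3, a zinc-finger transcription factor of the Krüppel-like family, and CBP, the histone acetyltransferase coactivator encoded by CREBBP, were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary human epidermal keratinocytes at day 3 of differentiation. CBP was mapped again in keratinocytes in which KLF3 had been knocked down. The 8 libraries comprised 2 of KLF3 ChIP, 2 of CBP ChIP, 2 of CBP ChIP after KLF3 knockdown and 1 input each for the KLF3 and the CBP experiments. The questions were where KLF3 and CBP bound, how often they shared a site, and which CBP sites changed when KLF3 was depleted. The deposited tables gave 1 list of KLF3 peaks, 1 list of CBP peaks and 1 list of regions with changed CBP signal, each with 1 value per peak or region. Values per library, read depth and the level of KLF3 after knockdown were not analysed here. Every test below takes peaks, regions or genes as its unit, and no error between replicates can be given. Positions are on hg19.

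KLF3 bound mainly at and near gene starts. The KLF3 list held 25334 peaks on chromosomes 1 to 22 and X, and 12120 of them, 47.8% (exact 95% interval 47.2 to 48.5), lay within 1 kb of a transcription start site. The highest peak scores, which are the authors' own values per peak, stood at the promoters of GPC1 (144.95, chromosome 2, 241374720 to 241375055), ECHDC3 (126.25), ABTB1 (124.95), KLF3 itself (123.3), CBX3 (121.9) and SREBF1 (114.25), the last a master regulator of lipid synthesis. MCRIP1 (113.95), PQLC3 (112.65), LRFN4 (112.5) and PCNT (110.2) completed the 10 highest, all within 1 kb of a start site. Promoter KLF3 peaks had a median score of 20.45 and distal peaks one of 11.7.

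CBP bound mainly away from gene starts. Of 24315 CBP peaks, 3012 lay within 1 kb of a start site, a share of 12.4%, and 30.1% lay more than 50 kb from one, against 12.5% of KLF3 peaks. The strongest CBP peak of all (score 64.1, chromosome 4, 38665497 to 38665802) was at the KLF3 promoter, at -141 bases from the start site. Others of the 10 strongest were assigned to CD55 (63.3), KLF9 (62.55), KPNA7 (58.7) and KRT80, an epidermal keratin (58.65), and to the noncoding genes LOC100130987, LINC01588, MIR5684, PCAT1 and LOC101927630. The median CBP score was 10.4 at promoters and 11.35 at distal sites. The odds of a promoter position were 6.49 times higher for KLF3 peaks than for CBP peaks (Woolf 95% interval 6.20 to 6.79, Fisher's exact test, two-sided).

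**Figure D1:**
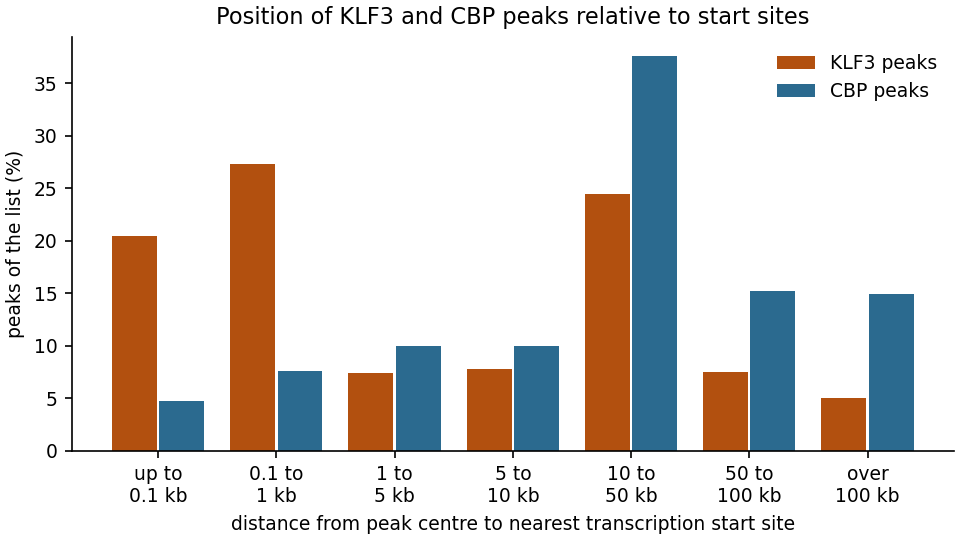
Share of the 25334 KLF3 peaks and the 24315 CBP peaks, in percent of each list, by distance from the peak centre to the nearest transcription start site in kb. KLF3 peaks are most frequent within 1 kb (47.8% against 12.4% of CBP peaks) and CBP peaks beyond 10 kb.

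KLF3 and CBP shared 8489 of the KLF3 peaks, 33.5% (32.9 to 34.1), by an overlap of at least 1 base. Co-bound sites included the promoters of DSP, which encodes the desmosomal plaque protein desmoplakin (KLF3 score 90.85, CBP score 38.75), ITGA2, an integrin subunit (86.65 and 16.4), and TNFAIP3, an inhibitor of NF-kappaB signalling (72.9 and 20.45). A site at -2192 bases from the start of IVL, which encodes the envelope precursor involucrin, carried a KLF3 peak of score 21.8 and a CBP peak of score 49.65 (chromosome 1, 152878612 to 152879047). At KLF3 the promoter peaks of both factors overlapped, as did a pair of weaker peaks upstream (15.7 and 32.45). At CREBBP a KLF3 peak at -752 bases from the start (24.5) overlapped a weak CBP peak (6.52). No peak of either list was assigned to EP300, the paralogue of CREBBP. Rotating the KLF3 list along the chromosomes gave a mean overlap of 0.624%, so the observed share was 53.7-fold higher (permutation by rotation, p = 0.001, one-sided, the smallest that 1000 rotations can give). Rotation ignores chromatin accessibility, so this fold cannot tell sharing specific to KLF3 and CBP from that of any factors at accessible sites. In the other direction 34.9% of CBP peaks (34.3 to 35.5) overlapped KLF3.

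Sharing differed between promoters and distal sites. Of distal KLF3 peaks 46.9% (46.0 to 47.7) overlapped a CBP peak, against 18.9% (18.2 to 19.7) of promoter KLF3 peaks, an odds ratio of 3.77 (3.57 to 3.99). Among CBP peaks the order was the other way round, with 75.3% of promoter peaks (73.8 to 76.9) and 29.1% of distal peaks (28.5 to 29.8) on a KLF3 peak. CBP peaks that overlapped KLF3 had a median score of 13.0 and the others one of 10.5.

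Genes of keratinocyte adhesion and transcription carried KLF3 in nearly every case. Of 24 desmosome and adherens junction genes 23 had a KLF3 peak assigned to them and 20 a co-bound site, including DSP, CTNNA1, DSG2 and PKP2. The share was 20 of 21 for AP-1 and immediate early genes, 29 of 32 for epidermal transcription factors, 24 of 26 for TGF-beta and BMP pathway genes and 19 of 21 for basal keratinocyte and hemidesmosome genes, with PLEC, COL7A1 and ITGB4 among the co-bound members. Among all 20056 protein-coding genes 59.5% had a KLF3 peak, and these 5 lists exceeded it with Benjamini-Hochberg adjusted p of 0.000881, 0.00155, 0.00125, 0.00155 and 0.00761 (Fisher's exact test, two-sided, over 20 lists). Suprabasal keratins and late differentiation enzymes (28 of 35, adjusted p = 0.0331), lipid barrier genes (24 of 30, adjusted p = 0.0447) and extracellular matrix and motility genes (24 of 30, adjusted p = 0.0447) also passed the exact test. With peaks limited to 1 kb around the start site, the odds ratios of those last 3 lists and of the epidermal transcription factors fell below 1, at 0.563, 0.826, 0.826 and 0.953, and the AP-1 and basal keratinocyte lists kept odds ratios above 1 (1.44 and 2.70) but no longer passed the exact test (adjusted p = 0.685 and 0.0851). Within 10 kb the AP-1 and basal keratinocyte lists still passed the exact test (odds ratio 5.13 and adjusted p = 0.00997 each). The other lists of these 6 did not (adjusted p from 0.158 to 0.559). These limits leave fewer peaks per gene, and near and far peaks were not compared by a test.

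Cornified envelope precursors stood apart, with a KLF3 peak at 14 of 41 genes (Fisher's exact test, odds ratio 0.352, adjusted p = 0.00352) and none at FLG or HRNR, a pair of envelope genes picked out after the values were seen. Immune and Langerhans cell markers (2 of 15, adjusted p = 0.00155) and hepatocyte genes (2 of 20, adjusted p = 0.000122) were likewise below the share of all genes in the exact test. Notch pathway genes (17 of 21), EGFR ligands and receptors (12 of 15), coactivators and KLF3 partners (16 of 20), cell cycle and replication genes (23 of 32), inflammation and interferon genes (19 of 30), ribosomal protein genes (21 of 40), melanocyte markers (8 of 15), fibroblast markers (9 of 15) and neuronal genes (12 of 20) did not pass. With peaks within 1 kb, neuronal genes (odds ratio 0.120) and melanocyte markers (0.166) passed as depleted and EGFR genes (4.32) as enriched in the exact test (adjusted p = 0.00237, 0.0266 and 0.0442), and with peaks within 10 kb so did Notch genes as enriched (3.64, adjusted p = 0.0368). A CBP peak was assigned to 40.7% of coding genes, and 11 lists differed from that share. Ribosomal protein genes lay below it (7 of 40, exact test, adjusted p = 0.00636). Among the 10 lists above it were epidermal transcription factors (29 of 32, exact test, adjusted p = 1.04e-07), basal keratinocyte genes (20 of 21, adjusted p = 1.76e-06) and fibroblast markers (11 of 15, adjusted p = 0.0278), the last with odds ratios below 1 when peaks were limited to 10 kb or 1 kb around the start site (0.794 and 0.235). With peaks within 1 kb 6 lists passed, and those of the lipid barrier, EGFR, TGF-beta and BMP and matrix genes no longer did. Co-bound sites, found at 23.2% of genes, were enriched in 9 lists, among them desmosome genes (20 of 24, exact test, adjusted p = 1.52e-08), and cornified envelope genes were not among them (10 of 41, adjusted p = 0.948). With peaks within 1 kb, which leaves fewer peaks per gene, only 2 co-bound lists passed. A gene with more space around it can be assigned more distal peaks, which these tests do not correct for.

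After KLF3 knockdown CBP signal fell in 1591 regions and rose in 2177, per the authors' deposited table, which lists significant regions only. Regions of falling signal are called lost and those of rising signal gained, although most lost regions kept part of their signal: the median log2 fold change of the lost regions in the authors' deposited table was -0.98, that is 50.7% of the control level, and that of the gained regions was 1.34. The strongest losses in the authors' deposited table were nearest to AQP7, an aquaglyceroporin gene (-2.25, deposited p = 1.4e-08), VAV3 (-2.12), RDH14 (-1.91), PUM3 (-1.90) and HK2, a hexokinase gene (-1.85). The strongest gains in the authors' deposited table were nearest to NOS1AP (3.13, deposited p = 4.1e-11), LINC01148 and LINC01774 (both 2.07), IGFBP3 (2.06) and GSX2 (2.05). The lost regions named here lay 29.8, 160.3, 158.4, 86 and 26 kb from those start sites in that order. The gained regions lay 100, 418.8, 49.5, 8.5 and 16 kb away in the order named. Nearest refers to recovered start sites only, so a gene without a recovered site may lie closer. The gene named need not be the gene that a region acts on. None of the 10 strongest losses and none of the 10 strongest gains overlapped a KLF3 or a CBP peak. Lost regions made up 42.2% of all (40.6 to 43.8), and 28.8% (27.1 to 30.6) of those with an absolute log2 fold change of at least 1, of which 753 were lost and 1858 gained. Among changed regions at a CBP peak the balance turned, with 1167 lost and 201 gained, 85.3% lost (83.3 to 87.1), a restriction that favours losses by construction because the peaks were called without knockdown. Among regions longer than 1000 bases, a limit chosen after the data were seen, 53.1% were lost.

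Most lost regions lay at called CBP peaks and fewer than that at KLF3 peaks, while gained regions seldom lay at either. A CBP peak overlapped 73.4% of lost regions (71.1 to 75.5) and 9.23% of gained regions (8.05 to 10.5), an odds ratio of 27.1 (22.5 to 32.5). Since the CBP peaks were called in libraries without KLF3 knockdown, a region that loses signal is more apt to hold a called peak than one that gains it. This contrast thus follows at least in part from how the lists were made, and how large that part is was not measured. A KLF3 peak overlapped 43.9% of lost regions (41.5 to 46.4) and 4.64% of gained regions (3.79 to 5.61), an odds ratio of 16.1 (12.9 to 20.1, Fisher's exact test, two-sided, p = 1.2e-196). Rotated regions met a CBP peak in 1.56% and 1.28% of cases and a KLF3 peak in 1.76% and 1.32% for lost and gained regions respectively, and all 4 observed shares were higher (permutation by rotation, p = 0.001 each, the smallest that 1000 rotations can give). Limited to changed regions at a CBP peak, KLF3 was present in 54.0% of lost (51.1 to 56.9) and 18.4% of gained regions (13.3 to 24.5), an odds ratio of 5.20. The odds ratio of 16.1 over all regions thus takes in the CBP contrast and its built-in part, since 33.5% of KLF3 peaks overlapped a CBP peak. Promoters held 7.29% of lost and 3.77% of gained regions (odds ratio 2.01, Fisher's exact test, two-sided, p = 2.66e-06).

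**Figure D2:**
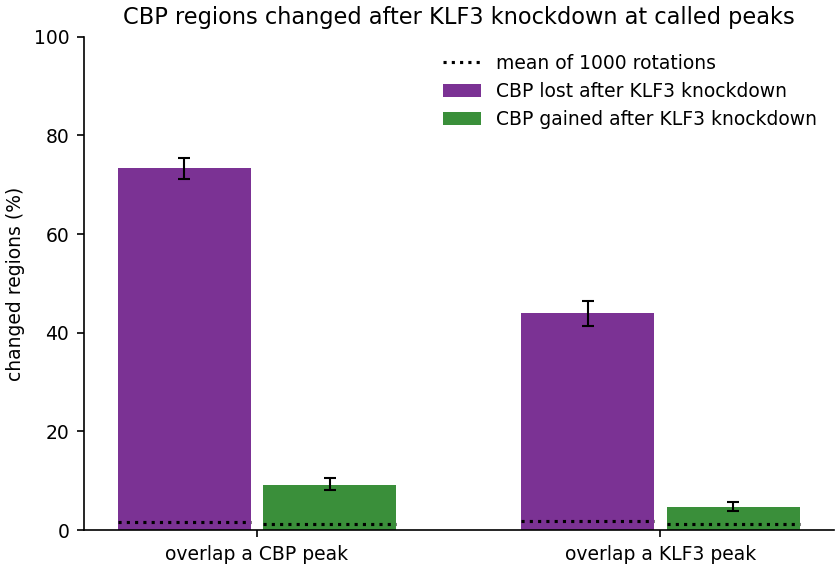
Share of lost (1591) and gained (2177) CBP regions, in percent, that overlap a called CBP peak or a KLF3 peak; bars are shares, error bars exact 95% intervals over regions and dotted lines the mean of 1000 rotations. Lost regions overlap CBP peaks in 73.4% and KLF3 peaks in 43.9% of cases, gained regions in 9.23% and 4.64%.

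CBP peaks bound by KLF3 were lost more often than other CBP peaks. Of 8476 CBP peaks that overlapped KLF3, 7.40% lay in a lost region (6.85 to 7.98), against 3.88% (3.59 to 4.20) of the 15839 others. Peaks of this kind included the upstream site of IVL, the promoter site of SMPD1, which encodes acid sphingomyelinase, and sites assigned to CALML5, KLF10 and NOTCH3. The fall was small at KLF10 and NOTCH3, with log2 fold changes of -0.49 and -0.3 in the authors' deposited table. Regions of small change were kept in these counts. Against CBP peaks in no changed region the odds ratio for KLF3 was 1.97 (1.75 to 2.20, Fisher's exact test, two-sided, p = 2.1e-30). It was 2.45 (2.17 to 2.76) at distal peaks, where 8.97% of co-bound and 3.85% of other CBP peaks were lost. At promoters the order was the opposite, with 3.09% of co-bound and 4.58% of other CBP peaks lost, an odds ratio of 0.656 (0.432 to 0.998) that did not pass Fisher's exact test (p = 0.0623), and the distal and promoter odds ratios differed (normal test of the difference of log odds ratios, two-sided, p = 3.1e-09). Loss also rose with CBP score, from 1.43% in the lowest decile to 11.6% in the highest. Scores and losses may rest on the same CBP ChIP libraries, so they may not be independent. In the highest decile 14.7% of co-bound peaks (13.0 to 16.7) and 6.93% of the others (5.41 to 8.72) were lost. In the 3 lowest deciles there was no such excess, with 0.723%, 1.94% and 2.64% of co-bound and 1.63%, 1.895% and 2.77% of other peaks lost. Whether the odds ratio changes with score was not tested. With score decile as a stratum, added after the data were seen, the odds ratio was 1.54 (1.36 to 1.73).

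**Figure D3:**
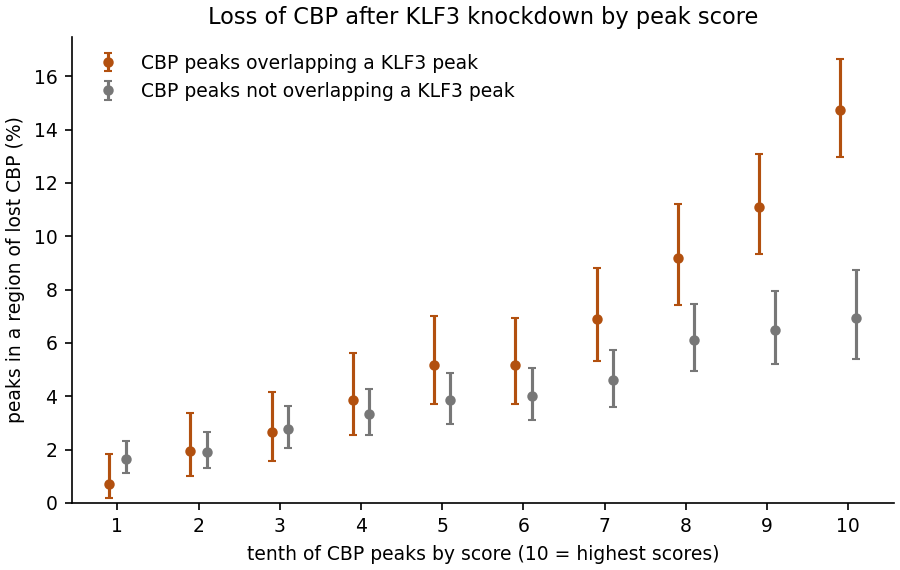
Share of CBP peaks in a lost region, in percent, by decile of CBP peak score from 1 (lowest) to 10 (highest), for peaks that overlap a KLF3 peak and peaks that do not; error bars are exact 95% intervals over peaks. Both shares rise with score, to 14.7% with KLF3 and 6.93% without it in decile 10, and the share with KLF3 is no higher than that without it in deciles 1 and 3.

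Suprabasal, late enzyme and lipid barrier genes lay at lost regions more often than other genes. Of 29 suprabasal keratin and late enzyme genes with a CBP peak or a changed region, 14 had a lost region, against 1022 of the 8540 background genes (odds ratio 6.95, 3.34 to 14.4, Fisher's exact test, two-sided, adjusted p = 1.5e-05). In the authors' deposited table the log2 fold change was -1.41 near KRT80 (deposited p = 5.2e-08), -1.35 near CALML5, a calmodulin-like protein of differentiating keratinocytes, -1.27 for SPINK5, which encodes the protease inhibitor LEKTI (61.4 kb from the start site), and -1.19 near the tight junction gene CLDN4. The regions named for CALML5 and CLDN4 overlapped no CBP peak. Another lost region of CALML5, at a CBP peak, had -0.61 in the authors' deposited table. Of the 14 genes 11 had a lost region at a CBP peak. TGM1, KRT78, PADI1, KRTDAP, SBSN, DMKN, TGM5, ASPRV1, CST6 and S100A7 were the other members with a lost region. KRT1 had a gained region (1.41 in the authors' deposited table) and no lost one. KRT80 also had a gained region (0.18) with KLF3 and CBP peaks, 0.1 kb from its start site. The suprabasal keratins KRT10, KRT2 and KRT77, picked out after the values were seen, were assigned no CBP peak and no changed region. They were thus not among the 29. Of 26 genes of the epidermal lipid barrier 11 had a lost region (odds ratio 5.44, 2.49 to 11.9, exact test, adjusted p = 0.000637). TGM1 is in both this list and the suprabasal one and was counted in each. The authors' deposited table gave -1.48 near ALOX12B, a lipoxygenase gene, -1.33 near NIPAL4, -1.29 at a region with KLF3 and CBP peaks near CYP4F22, an omega-hydroxylase gene of acylceramide synthesis (chromosome 19, 15621701 to 15623600, deposited p = 1.6e-08), and -1.18 near SPTLC3, a serine palmitoyltransferase subunit. The region named for ALOX12B overlapped no CBP peak, but all 11 genes had a lost region at one. Gained regions of this list were assigned to FA2H (1.37, 94.9 kb away), SGMS1 (1.22, 119.8 kb away) and LIPM (0.88), which also had a lost region.

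Epidermal transcription factors were the list with the largest share at lost regions, 19 of 30 genes (odds ratio 12.9, 6.13 to 27.2, exact test, adjusted p = 7.8e-10), and 12 of the 19 had a KLF3 peak inside a lost region. Stratified by the number of CBP peaks per gene, the odds ratio fell to 4.73 (18 of 29 genes against 8.16 expected, exact test, adjusted p = 0.00118), below the 6.24 of suprabasal genes and above the 4.08 of lipid barrier genes. Of the 19 genes 6 also had a gained region, among them HOPX, PRDM1, ZNF750 and KLF10. The authors' deposited table gave -1.51 at a co-bound region near HOPX (chromosome 4, 57551901 to 57554000, deposited p = 3.3e-09), -1.24 for PRDM1, which encodes BLIMP1, -1.24 for GATA3 and -1.13 for KLF6. Distances to the start sites were 5, 23.5, 86.3 and 102.3 kb in that order. The regions named for PRDM1 and GATA3 overlapped no CBP peak. Of the 19 genes 17 had a lost region at a CBP peak. GRHL1, GRHL3, OVOL2, ZNF750, MAF, KLF9, KLF10, CEBPA, TFAP2C, FOXN1, EHF, ELF3, SOX9 and HES1 were among the rest. The change was not large in all of them: the authors' deposited table lists -0.49 at KLF10 and -0.09 at KLF9. AP-1 and immediate early genes had a lost region at 8 of 19 genes (odds ratio 5.38, 2.16 to 13.4, exact test, adjusted p = 0.00459), among them EGR1 (-1.04 in the authors' deposited table), DUSP6 (-1.03), EGR3 (-0.94) and DUSP4 (-0.93). Those regions lay 26.7, 118.4, 51.9 and 191.7 kb from the start sites in that order, and those of EGR1 and EGR3 overlapped no CBP peak. Of the 8 genes 7 had a lost region at a CBP peak. IER5 was counted through 1 region of -0.28 in the authors' deposited table (deposited p = 0.0535), and JUNB through 1 of -0.45. DUSP4 and DUSP5 also had a gained region, of 1.59 and 1.26 in the authors' deposited table. That call ended when the 18 of these genes with a CBP peak were stratified by their number of CBP peaks, an alternative chosen after the data were seen (8 genes against 3.28 expected, odds ratio 4.61, exact test, adjusted p = 0.0665). It also ended when regions were limited to 50 kb around the start site (odds ratio 3.39, exact test, adjusted p = 0.148). The other 3 lists passed in both.

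The remaining lists did not pass for lost regions. Cornified envelope precursors had one at 5 of 22 genes (adjusted p = 0.498), namely IVL, CRNN, CDSN, PRR9 and SPRR4, with log2 fold changes of -0.66, -1.30, -1.06, -1.06 and -0.78 in the authors' deposited table, taking the strongest region of each. Those regions of CRNN and CDSN overlapped no CBP peak. LOR, which encodes loricrin, was not among the genes tested, because its name is shared with another gene in the table of symbols. Its single CBP peak lay in a lost region, and with shared names resolved by chromosome, an alternative chosen after the data were seen, the count was 6 of 23 (odds ratio 2.60, exact test, adjusted p = 0.197). Basal keratinocyte and hemidesmosome genes had one at 2 of 20, ITGB1 and ASS1. The counts were 4 of 22 for desmosome genes, 3 of 12 for the Notch pathway, 2 of 14 for EGFR ligands and receptors, 2 of 21 for the TGF-beta and BMP pathway, 1 of 24 for extracellular matrix and 1 of 11 for coactivators and KLF3 partners. None was seen at 15 cell cycle, 18 inflammation and interferon or 9 ribosomal protein genes. Among markers of other cells the counts were 1 of 12 for fibroblasts and 0 of 6 each for melanocytes and immune cells, with 2 of 8 neuronal and 0 of 5 hepatocyte genes. With names as matched, the p-values of these lists lay at or above an adjusted 0.498.

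No list passed for gained regions (0 of 20 lists by Fisher's exact test, 2 of 20 at an unadjusted p below 0.05), where the background share was 16.7%. The 2 were basal keratinocyte and hemidesmosome genes (8 of 20, odds ratio 3.35, exact p = 0.0111, adjusted p = 0.111) and epidermal transcription factors (11 of 30, odds ratio 2.91, exact p = 0.0108, adjusted p = 0.111), and both passed against a background of all annotated genes. Stratified by the number of CBP peaks per gene, the odds ratio was 3.49 for the basal list (8 genes against 3.49 expected, exact p = 0.0241, adjusted p = 0.482) and 1.71 for the factors (11 genes against 7.95 expected, exact p = 0.268), and neither passed. The authors' deposited table listed 1.40 for CAV1 (34.8 kb from the start site), 1.39 for DST (28.7 kb), 1.36 for TP63, the master regulator of basal keratinocytes (82.4 kb), and 1.31 for LAMA3 (4.1 kb). For the factors it listed 1.62 for RUNX1 (66.2 kb) and ZNF750 (9.6 kb), 1.55 for TRPS1 (80 kb) and 1.41 for KLF4 (153.1 kb). These 8 regions lay outside CBP peaks and, except for that of ZNF750, outside KLF3 peaks. TP63 is in both the basal list and that of the factors and was counted in each. CREBBP had gained regions of 0.98 and 1.29 in the authors' deposited table. Fibroblast markers had a gained region at 4 of 12 genes, with FBN1 (1.89, 92.9 kb away) and DCN (1.54, 427.6 kb away) in the authors' deposited table, melanocyte markers at 1 of 6, and immune markers at 0 of 6. The count was 6 of 18 for inflammation genes, with TNFAIP3 (1.47, 60.8 kb away) and IL1B (1.42, 33.7 kb away) in the authors' deposited table, 2 of 22 for cornified envelope precursors and 2 of 29 for suprabasal genes.

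**Figure D4:**
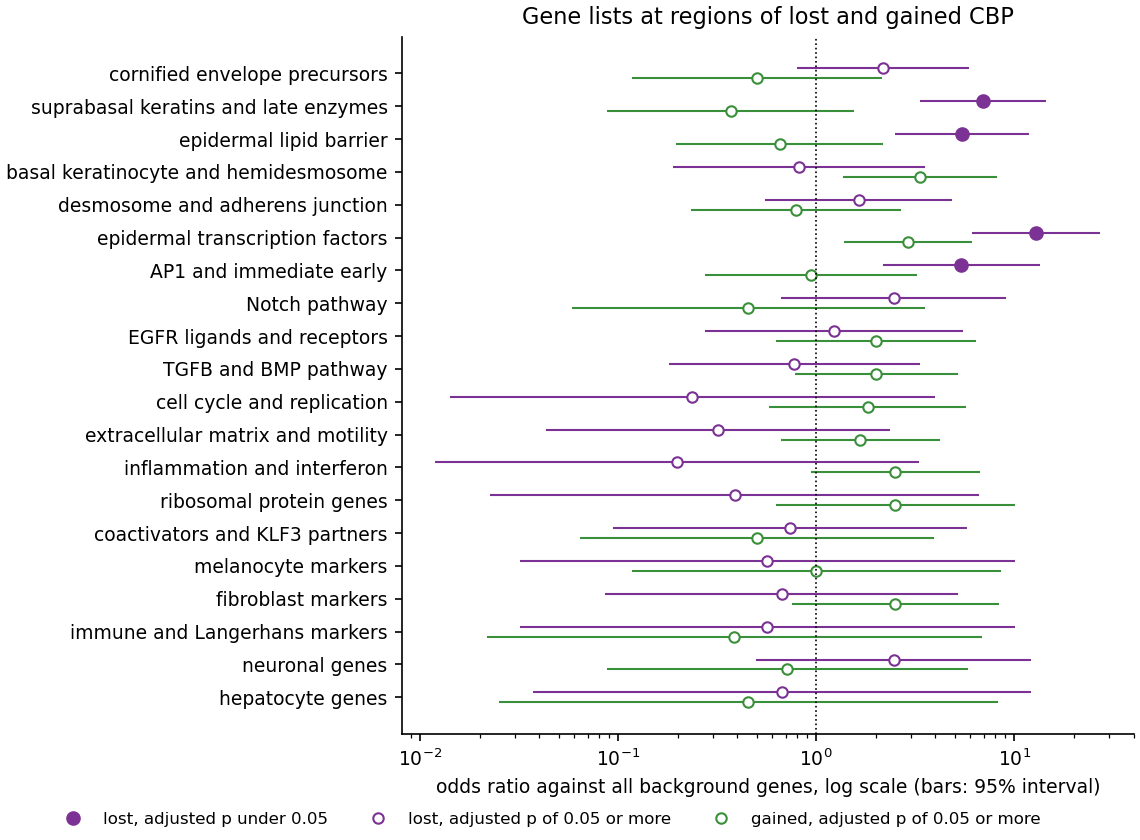
Odds ratio (log axis) of having a lost or a gained CBP region for the members of 20 gene lists against 8540 background genes; bars are Woolf 95% intervals, with 0.5 added to each cell where a list has no such member, and filled points have an adjusted p below 0.05. The 4 filled points, between 5.38 and 12.9, are all for lost regions.

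The epidermal differentiation complex on chromosome 1, a cluster of genes for the cornified envelope and S100 proteins, held 49 KLF3 peaks, 69 CBP peaks, 12 lost and 5 gained regions between 151.95 and 153.65 Mb. In the authors' deposited table the region over the co-bound upstream site of IVL had a log2 fold change of -0.66 (152877601 to 152879800, deposited p = 5.7e-11). Losses in the authors' deposited table were also assigned to CRNN (-1.18 and -1.30), CRCT1 (-0.88), S100A11 (-0.06), SPRR4 (-0.78 and -0.72), PRR9 (-1.06), PGLYRP3, which encodes a peptidoglycan recognition protein (3 regions, from -1.07 to -0.77, of which 1 covers the CBP peak that the authors assign to LOR), and S100A7, which encodes psoriasin (-0.98). Gains there were assigned to RPTN (1.11 and 1.07), CRNN (1.11), which thus had regions of both kinds, S100A10 (1.29) and S100A2 (1.02) in the authors' deposited table.

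**Figure D5:**
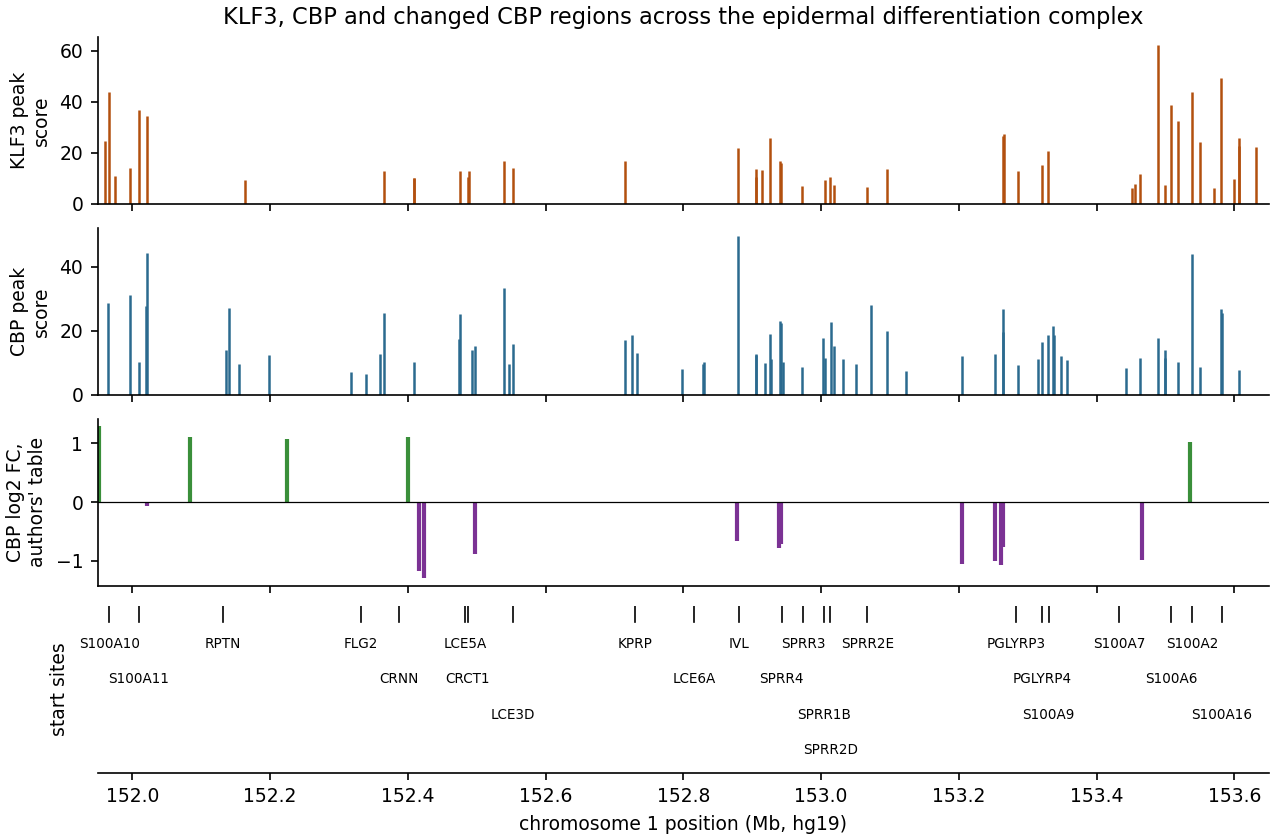
Map of chromosome 1 from 151.95 to 153.65 Mb (hg19) with the scores of the 49 KLF3 and 69 CBP peaks, the log2 fold change of the 12 lost and 5 gained CBP regions in the authors' deposited table, and start sites recovered from the deposited distances; lines stand at peak and region centres and their widths are not to scale. The tallest CBP line, of score 49.65, is upstream of IVL and has a lost region over it.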

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

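The tests stratified by CBP score, crowding or number of CBP peaks, and those on promoter CBP peaks alone, on regions longer than 1000 bases, on a deposited p under 0.0001 and with shared gene names resolved, were chosen only after the results were seen. Of 68 alternatives to the main results, 56 kept the direction and the side of the threshold, or a count within 1.5 times. The promoter odds ratio of KLF3 over CBP peaks ranged from 5.66 to 15.4, the fold of KLF3 and CBP overlap over rotation from 37.8 to 93.3, the odds ratio of KLF3 in lost against gained regions from 5.20 to 22.2, and that of CBP peaks from 31.2 to 32.2. At or above the median score, 64.9% of KLF3 and 10.7% of CBP peaks were at promoters. With an absolute log2 fold change of at least 1, 753 lost and 1858 gained regions were left, 28.8% lost. Among regions at CBP peaks 85.3% were lost and 201 were gained, and among those longer than 1000 bases 53.1% were lost and 1027 were gained, both opposite to the balance over all regions, the former favoured by construction because the peaks were called without knockdown. The odds ratio of KLF3 at lost CBP peaks was 1.504 to 2.45 over the other alternatives, but 0.656 at promoter peaks alone and 0.681 there with score strata. With peaks within 1 kb of the start site, KLF3-bound odds ratios were 0.563 for suprabasal genes, 0.826 for both lipid barrier and matrix genes and 0.953 for transcription factors, and the co-bound one was 0.656 for matrix genes. CBP-bound fibroblast markers fell to 0.794 within 10 kb and 0.235 within 1 kb. Within 1 kb, 6 CBP-bound lists passed (11 with all peaks) and 2 co-bound lists (9 with all peaks), from fewer peaks per gene. With all annotated genes as background 2 lists passed for gained regions, basal keratinocyte genes and epidermal transcription factors, since that background adds genes with no CBP peak. Apart from these constructions, the cause was not tested. No paired analysis was possible because the deposited tables hold 1 value per peak or region and none per library, and for the same reason no library was left out in turn. Motif alternatives, another source of start sites, random placement within a class, lists matched on gene spacing, and adjusted p limits (the deposited p was used) were not run. Read depth is unknown, so its effect on which peaks and regions were called cannot be given.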

Other observations

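The tests of CBP score strata, of off-peak gains against rotated positions, of lower enrichment at every CBP peak, and of gained regions without the highest score decile were chosen only after the results were seen. By the authors' deposited table, a group of 39 genes had at least 3 lost regions. ASAP1 and NUAK1 had 4 each with no KLF3 peak in any, and KAZN, which encodes the junction protein kazrin, had 4 that all held a KLF3 peak, with log2 fold changes from -0.98 to -0.62 in the authors' deposited table. Both KAZN and NUAK1 also had gained regions, 3 at KAZN (1.34, 1.38 and 1.56 in the authors' deposited table) and 1 at NUAK1 (1.21). TOB1, an antiproliferative gene, had 3 that all held one, as did KRT78. A lost region was found at 14 of 29 suprabasal and 2 of 20 basal keratinocyte genes, and a gained region at 2 of 29 and 8 of 20, a pair of lists set side by side after their counts were seen. KLF3's own promoter, with the strongest CBP peak, lay in no changed region.

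Gained regions mostly lay outside called CBP peaks, which is in part built in, since the peaks were called without knockdown. Random scatter as the source of every gained region is argued against, since 9.23% met a CBP peak and at most 2.20% did in 1000 rotations. Of those off CBP peaks, 3.04% met a KLF3 peak outside CBP peaks against at most 1.72%. Scatter as the source of most off-peak gains is not excluded, since most of them met no KLF3 peak. Rotation also does not leave out sequence in which no region can be called. The share of 3.04%, with an upper bound of 3.89%, argues against KLF3-bound sites without a CBP peak as the main source of off-peak gains. Calls from windows with few reads may account for part of them, since 58.1% of off-peak gained regions shared their p-value with another region, against 15.7% of lost and 16.4% of gained regions at CBP peaks, but off-peak lost regions did so in 37.97% of cases, so this goes with lying off peaks as well as with gain. Lower enrichment over background in the knockdown libraries cannot be told apart from a gain of CBP: stronger CBP peaks were in gained regions somewhat more often (odds ratio 1.43, 1.08 to 1.89), but this rested on the highest score decile (1.16, 0.850 to 1.58, without it) and bears on gains at peaks rather than off them, so the bound set beforehand was too weak to decide.

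CBP peaks that overlapped KLF3 were more often lost. Peaks of higher score being called more easily is argued against as the whole cause, since the odds ratio was 1.54 (lower bound 1.36) within score deciles, although it fell from 1.97. Crowding of CBP peaks is argued against by an odds ratio of 1.98 (lower bound 1.76) within crowding strata. No biological explanation was tested. Chromatin accessibility, other factors at the same sites and indirect effects of the knockdown were not measured and remain open, and 3.88% of CBP peaks without a KLF3 peak were lost as well.

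The relation held at distal and not at promoter CBP peaks. Weaker promoter peaks are argued against, since the odds ratios still differed within score deciles (p of the difference = 1.18e-05). Whether a fall of enrichment at every CBP peak in the knockdown libraries played a part cannot be decided. The distal odds ratio was 1.84 (lower bound 1.62) within score deciles. A general fall is called more easily where reads are many, and peaks with and without KLF3 could not be matched on reads. No biological explanation of the difference was tested, and an effect of promoter sharing among many factors was not tested either.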
